A study of Mus musculus with 20 samples.

How the data were processed

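The series profiled hematopoietic stem cells (HSC) sorted from adult mice that had been given poly(I:C), which switches on the Mx1-Cre transgene. Control mice carried floxed Mtor alleles and no Cre (WT), knockout mice carried the floxed alleles and Mx1-Cre (KO), and a further group carried in addition 1 floxed allele of c-Myc (KO MycHet). Of the 20 samples, 12 had a peak list that was used here: ChIP-seq of H3K27ac, H3K4me3 and MYC with 1 WT and 1 KO library each, and ATAC-seq with 2 WT, 2 KO and 2 KO MycHet libraries, made from 50000 cells per library per the labels. The other 8 samples, RNA-seq of 4 WT and 4 KO mice per the labels, were not analysed here.

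Each list held the peaks of 1 library, so peaks were called per sample and not on pooled samples. Each peak had a chromosome, a start, an end, a name of the form given by the MACS peak caller and a score, and the score is the value the authors deposited from their peak caller. No deposited score was below 50, and no label states its scale. It was used to describe and rank peaks within a list. Some filters put 1 score level on several lists, which takes their scores to be on the same scale, and this was not checked. The genome build was mm10, and CASAVA, TopHat and Cufflinks were the tools named, per the submitters' processing notes. The aligner of the ChIP-seq and ATAC-seq reads, the version and settings of the peak caller, the use of an input control and the handling of ATAC-seq reads are not given in the sources used here. The lists give no read counts, so the depth of each library is unknown, and a longer list can come from a deeper or cleaner library as well as from more marked regions. Shares are given with exact Clopper-Pearson 95% confidence intervals (CI), which cover counting error only.

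Peaks on chromosomes 1 to 19 and X were kept, and those on Y were left out. Peaks were taken as overlapping when they shared at least 1 bp. Gene positions came from a table of the GRCm38.p6 assembly, the assembly also called mm10, with 21631 protein-coding genes on these chromosomes. That table gives no strand, so the promoter fixed in the design (1 kb around a transcription start) was replaced by a window of 1 kb around either annotated end of a gene. This is a departure from the design. Of 12075 genes with an H3K4me3 peak at an end, 10604 had it at 1 end and 1471 at both. "Lower" and "upper" below mean the end with the smaller and the larger coordinate. A gene was called KO only when a KO peak and no WT peak lay at either end, and WT only in the reverse case. ATAC-seq peaks of all 6 libraries were merged into 85640 regions. No genome sequence was used, so no motifs were searched.

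Before the data were examined, 22 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. Of 1848 listed genes, 1845 were matched by symbol. The lists covered the mTOR pathway, MNK, ERK and eIF4E signalling, P-TEFb and RNA polymerase II elongation, cell cycle, quiescence, HSC identity, oxidative phosphorylation (OXPHOS), glycolysis, ribosome biogenesis, MYC targets, ribosomal proteins, autophagy and lysosome, receptors and PI3K signalling, chromatin writers and erasers, and interferon response. They also held markers of erythroid, myeloid, B, T and NK, megakaryocyte, and stromal and endothelial cells, and olfactory receptors as genes silent in blood. The share of a list's genes that were KO only was ranked among 10000 random lists of the same size, matched on the number of histone marks at the gene (H3K27ac and H3K4me3 in both genotypes for MYC, H3K4me3 in both for H3K27ac, and no matching for H3K4me3). A list was said to stand apart above the 97.5th or below the 2.5th percentile. These percentiles describe the libraries at hand and are not p-values. MYC peaks were also placed at random 100 times on their own chromosomes. Overlap counts were checked against bedtools 2.31.1.

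The naming rule took Mtor and Myc, the 8 KO-only and 4 WT-only genes with the highest score for each ChIP target, up to 3 KO-only and 2 WT-only genes of each list for MYC and for H3K27ac, and the 8 and 4 genes with ATAC-seq peaks in both libraries of 1 genotype and neither of the other. It also took up to 10 genes that were KO only for all 3 ChIP targets and the 5 highest KO-only H3K27ac peaks away from gene ends. Predicted genes and RIKEN clones were left out. The text names a part of these genes, and the results of some are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

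With 1 ChIP-seq library per genotype and target there was no test between genotypes and no p-value. With 2 ATAC-seq libraries per genotype, the smallest two-sided exact permutation p is 0.33, so counts were set beside the other ways to pair the 4 libraries. The ranking of gene lists was tested on simulated genes in random classes of about equal size, without the peaks of any library. Of 100 lists of 40 genes given 3 times the share of new peaks, 99 lay above the 97.5th percentile among 21631 genes, as did 3 of 100 unchanged lists. The real classes differ in size, so these numbers need not hold for the MYC or H3K27ac ranking. Alternatives covered the score threshold, equal numbers of the highest-scoring peaks, the window, the overlap, the matching and leaving out each ATAC-seq library. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.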

Results

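Peak lists were compared for 12 libraries of sorted mouse HSC. H3K27ac, a histone mark of active promoters and enhancers, H3K4me3, a mark of active promoters, and the transcription factor MYC were each profiled in 1 WT and 1 KO library. Open chromatin was profiled by ATAC-seq in 2 WT, 2 KO and 2 KO MycHet libraries. On chromosomes 1 to 19 and X, the WT and KO lists held 10078 and 20036 H3K27ac peaks, 15089 and 16019 H3K4me3 peaks, and 8774 and 22086 MYC peaks. ATAC-seq lists held 17303 and 66531 peaks in WT libraries 1 and 2, 19174 and 72149 in KO libraries 1 and 2, and 47214 and 53722 in the KO MycHet libraries. Read depth is unknown for all 12, since peak lists carry no counts. The scores quoted are the authors' peak caller values, and their scale is not stated.

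**Figure D1:**
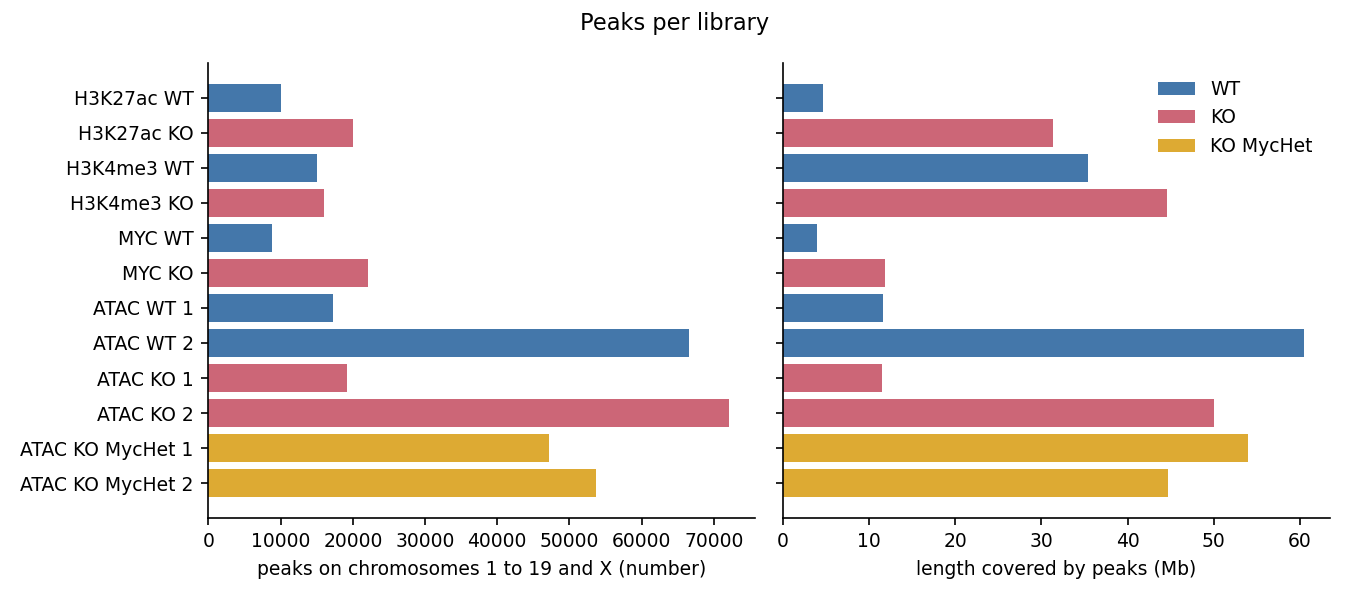
Number of peaks (left) and length covered by peaks in Mb (right) for each library on chromosomes 1 to 19 and X, coloured by genotype. KO lists were longer than WT lists for H3K27ac (20036 against 10078) and MYC (22086 against 8774), and WT 2 and KO 2 were the longest ATAC-seq lists.

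Mtor, the targeted gene and the kinase at the centre of the mTOR complexes, had peaks at its lower end in every WT library and in no library with the knockout. The gene (ID 56717) lies on chromosome 4 from 148448582 to 148557685 in mm10. All 5 WT libraries had a peak at the lower end, while none of the 5 KO and none of the 2 KO MycHet libraries had any. The WT peaks there scored 99.23 for H3K27ac, 155.44 for H3K4me3, 221.16 for MYC, and 341.21 and 1418.45 in ATAC-seq WT 1 and WT 2. Peaks elsewhere in the gene were present in all genotypes. An internal peak at 148509191 to 148510212 was found in 3 of 5 WT, 4 of 5 KO and 2 of 2 KO MycHet libraries, and the upper end had a peak in 2, 3 and 2 of them. Of the 768 ATAC-seq peaks of WT 2 that scored at least as high as the Mtor peak, 767 overlapped a peak of KO 2 and 767 a peak of KO 1, and the Mtor peak was the 1 that overlapped neither. This comparison with other peaks was chosen after the values were seen. Since the alleles are floxed, a missing peak at Mtor can mean sequence removed by Cre, which peak lists do not tell from a closed or unbound end.

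**Figure D2:**
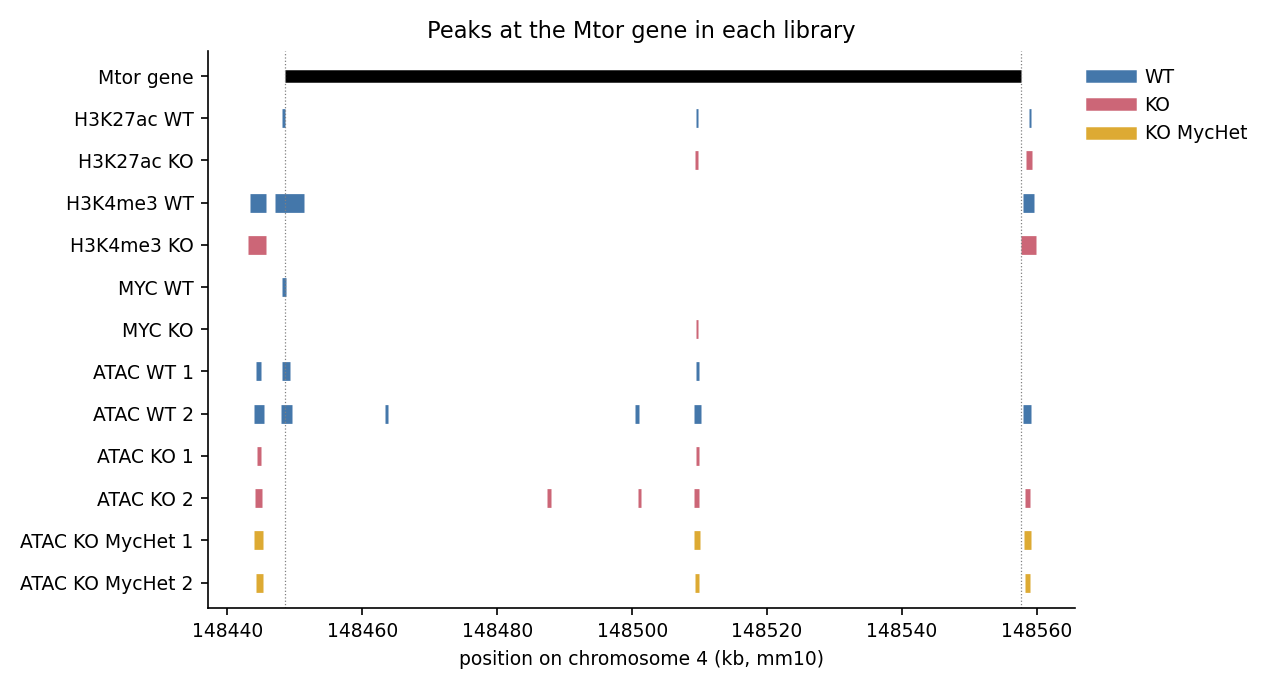
Peaks of each library along the Mtor gene, with position on chromosome 4 in kb of mm10 and the gene's annotated ends as dotted lines. Bars at the lower end (148448582) appear in the 5 WT libraries and in none of the 7 others.

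Myc (ID 17869; chromosome 15, 61985341 to 61990361), which encodes the factor immunoprecipitated here, was open in all 6 ATAC-seq libraries. Its lower end had an H3K27ac peak in KO only (score 160.27) and an H3K4me3 peak in WT only (164.57), the latter 7943 bp wide. No MYC peak lay at either end in WT or KO. The ATAC-seq scores at Myc were 142.26 and 441.64 in WT, 103.85 and 456.71 in KO, and 276.45 and 529.61 in KO MycHet libraries.

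H3K27ac was compared between WT and KO to ask how active regulatory regions differ without mTOR. The KO list held more and wider peaks. Most genes with a KO-only peak also had H3K4me3 at an end, among them interferon-stimulated genes, respiratory chain subunits and autophagy genes. Peaks numbered 20036 in KO and 10078 in WT, a ratio of 1.99, with a median width of 1237 bp against 333 bp and a covered length of 31.4 Mb against 4.71 Mb. A peak lay at an end of 8556 genes in KO and 3149 in WT, and 2983 genes had it in both, 5573 in KO only and 166 in WT only. Of the KO-only genes, 5326 had an H3K4me3 peak at either end in WT or KO, which need not be the end with the H3K27ac peak.

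Interferon response genes went from 5 of 34 with an H3K27ac peak in WT to 29 in KO, and the 24 KO-only genes placed the list at percentile 99.9 of random lists. Bst2, a membrane protein that tethers budding viruses (KO score 369.95), Gbp3, a guanylate-binding GTPase (261.93), and Trim25, a ubiquitin ligase of antiviral signalling (233.06), were among them. OXPHOS genes went from 23 to 69 of 75 (percentile 99.8), with the ATP synthase subunits Atp5h (502.55) and Atp5g2 (486.25) and the complex I subunit Ndufa10 (461.41). The Atp5h peak also lay at an end of Mrpl58, and that end of Atp5h had H3K4me3 in KO only. Autophagy and lysosome genes went from 8 to 31 of 33 (percentile 99.6), with Atg7 (482.76), which activates ubiquitin-like autophagy proteins, Wipi2 (311.03) and Map1lc3b (250.74). B cell markers went from 0 to 5 of 22 (percentile 98.3), among them the surrogate light chain genes Igll1 (176.69) and Vpreb1 (166.26) and the recombinase gene Rag2 (100.89). The Vpreb1 peak also lay at an end of Top3b. With equal numbers of peaks the autophagy list fell to percentile 95.2 and the B cell list to 73.1, so these lists no longer stood apart, whereas OXPHOS and interferon response still did.

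Other lists had more H3K27ac genes in KO without standing apart from random lists. Cell cycle genes went from 11 to 33 of 42, including the mitotic activator Cdc20 (403.02) and the replicative helicase subunit Mcm7 (351.53), and glycolysis from 3 to 17 of 24, including Pfkp (356.11) and Eno1 (278.29). MNK, ERK and eIF4E signalling went from 8 to 22 of 23 with Braf (323.81) and the cap-binding scaffold Eif4g1 (206.72). Ribosome biogenesis went from 21 to 41 of 44 with the nucleolar methyltransferase Fbl (469.52), ribosomal proteins from 46 to 77 of 84 with Rps7 (582.94), and MYC targets from 17 to 40 of 46 with Gart (387.24) and Ran (334.98). The mTOR pathway went from 10 to 20 of 28 with Akt2 (485.82) and Ulk1 (215.08), P-TEFb and elongation from 18 to 27 of 32 with Ccnt2 (344.07) and Cdk9 (313.67), and chromatin writers and erasers from 10 to 25 of 32 with Kdm6b (407.0). Receptors and PI3K signalling went from 7 to 19 of 32 with Cish (348.78) and Jak1 (226.53), and quiescence from 8 to 20 of 29 with Fbxw7 (288.0) and Rbl2 (248.73).

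HSC identity genes had an H3K27ac peak at 6 of 39 in WT and 14 in KO, at percentile 23.1 for KO-only genes. Runx1 (231.75), Ikzf1 (162.82) and Mecom (148.08) were KO only, while Spi1 (WT score 72.35) and Hoxb4 (56.33) were WT only. Markers of other cell types had peaks in WT and KO at the following numbers of genes: erythroid 0 and 5 of 24, myeloid 1 and 7 of 29, T and NK 1 and 4 of 27, megakaryocyte 1 and 8 of 20, and stromal and endothelial 0 and 3 of 20. Olfactory receptors had 4 and 5 of 1106, at percentile 0.0 for KO-only genes but at 35.3 among ends with H3K4me3. At Runx1, Ikzf1, Atp5h, Cdk9, Fbl and Kdm6b the KO peak overlapped a WT peak that ended outside the window. The KO peaks at Mcm7, Gart and Kdm6b also lay at ends of Ap4m1, Son and Dnah2.

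The KO-only genes with the highest H3K27ac scores included Ccdc15 (804.65), Tmco4 (707.76), the chaperone adaptor Stip1 (687.68), the glycogen synthase gene Gys1 (677.02), Lrrc75a (648.1), Clcn4 (642.03) and Cdc42ep5 (628.48). At all of these except Tmco4 and Gys1 the KO peak overlapped a WT peak that ended outside the window, so the gene end rather than the region was new in KO. The peaks at Stip1 and Cdc42ep5 also lay at ends of neighbouring genes. The WT-only genes with the highest scores were the chromatin remodeller Chd2 (270.7), Mtmr3 (219.08), Mid1 (213.5) and Samsn1 (198.76). Away from gene ends, the highest KO-only peaks lay on chromosome 16 at 17921061 to 17923480 near Slc25a1 (578.49), on chromosome 7 at 119719696 to 119721418 inside Thumpd1 (518.64), and on chromosome 16 at 21793295 to 21794770 near Ehhadh (498.99). A further pair lay on chromosome 3 at 63975877 to 63977599 inside Gmps (494.15) and on chromosome 4 at 148939927 to 148942395 inside Casz1 (490.11). All 5 were open in all 6 ATAC-seq libraries.

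Regions with H3K27ac in KO only were mostly open in the longer ATAC-seq lists of both genotypes, but not in the shorter ones. Of 15145 KO-only peaks, 76.8% (CI 76.1 to 77.4) overlapped an ATAC-seq peak of WT 2 and 76.5% one of KO 2, 42.0% one of WT 1 and 43.4% one of KO 1, and 3.02% were open in KO 2 and not WT 2. Of the 8165 genes with H3K4me3 in both genotypes and ATAC-seq peaks in all 4 WT and KO libraries, a set chosen after the peak numbers were seen, 31.8% (CI 30.8 to 32.8) had an H3K27ac peak in WT and 81.0% (80.1 to 81.8) in KO. Ribosomal protein genes within this set had one in 40 of 59 cases in WT and 59 of 59 in KO. WT peaks lay in open chromatin less often than KO peaks, 54.0% in ATAC-seq WT 2 against 79.7% in KO 2. The KO-only to WT-only gene ratio was 33.6, and 10.3 with equal numbers of peaks. With 1 library per genotype, no difference in H3K27ac, H3K4me3 or MYC could be set against a spread between replicates.

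MYC binding was compared between WT and KO because the series also includes mice with 1 floxed c-Myc allele. MYC peaks lay at more genes in KO, and the genes of ribosome production, the cell cycle and the MYC target list were over-represented among those that had a peak only there. The KO list held 22086 peaks and the WT list 8774, a ratio of 2.52. Genes with a peak at either end numbered 4831 in KO and 2225 in WT, of which 1716 were shared, 3115 KO only and 509 WT only. The KO-only to WT-only ratio was 6.12 with the full lists and 1.24 with equal numbers of the highest-scoring peaks (1226 and 992 genes).

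Ribosome biogenesis genes went from 10 of 44 with a MYC peak in WT to 33 in KO. The 26 KO-only genes, against 3 in WT only, put the list at percentile 100.0 of random lists, and at 99.78 with equal numbers of peaks (10 in WT and 19 in KO). Nat10, an RNA acetyltransferase (KO score 200.13), Nop16 (187.67) and the nucleolin gene Ncl (153.18) were KO only, and Noc2l (WT score 167.9) and Rrp9 (111.55) were WT only. Cell cycle genes went from 5 to 23 of 42 (percentile 99.6), with none in WT only. Among them were the kinase genes Cdk4 (198.67) and Aurka (168.86) and the helicase gene Mcm7 (171.6). MYC targets went from 13 to 30 of 46 (percentile 98.2), with the transcription factor gene Tfap4 (151.47) and the purine synthesis genes Paics and Ppat, which share 1 peak (113.06), while Odc1 (WT score 115.31) and Eif5a (87.13) were WT only. Erythroid markers went from 0 to 7 of 24 (percentile 99.9), including Car1 (87.61) and Ermap (78.62). At gene ends with H3K4me3 in both genotypes the cell cycle and erythroid lists lay at percentiles 87.2 and 73.0, and with equal numbers of peaks the erythroid list lay at 67.8.

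Genes of the mTOR pathway had about as many MYC peaks in KO as in WT, 11 and 12 of 28, and 11 in either without Mtor, the targeted gene. Rptor (123.31), the defining subunit of mTOR complex 1, and Akt1 (56.24) were KO only, and Mtor (221.16) and Pdpk1 (130.92) were among 3 in WT only. The list lay at percentile 1.1 for KO-only genes. It lay at 0.675 with matching on H3K4me3 score as well, and at 0.235 at ends with H3K4me3 in both genotypes. It lay at 14.4 with unmatched random lists, 7.2 with a window of 2.5 kb and 11.98 with equal numbers of peaks. With equal numbers, 12 of its genes had a MYC peak in WT and 8 in KO.

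The other lists of cell functions lay within the range of random lists for MYC. Glycolysis went from 0 to 8 of 24, with Pgam1 (109.37), the hexokinase gene Hk2 (108.36) and Pdk1 (101.97), and OXPHOS from 18 to 31 of 75, with Uqcrh (139.06), Sdhd (131.34) and the cytochrome c gene Cycs (122.02). Ribosomal proteins went from 25 to 46 of 84, with Rpl27 (246.32) and Rps19 (182.43). P-TEFb and elongation went from 10 to 19 of 32 with Nelfa (125.23) and Ell2 (119.34), MNK, ERK and eIF4E signalling from 5 to 10 of 23 with Eif4g2 (89.79), and autophagy and lysosome from 4 to 14 of 33 with Tfe3 (159.61). Interferon response went from 4 to 12 of 34 with Gbp3 (136.02) and Irf9 (102.15), receptors and PI3K signalling from 4 to 10 of 32 with Ptpn11 (122.46), and chromatin writers and erasers from 7 to 10 of 32 with Kdm6b (170.45). Quiescence genes went from 8 to 12 of 29, with the pocket protein gene Rb1 (79.3) in WT only. HSC identity genes had a MYC peak in 3 of 39 in WT and 6 in KO. Kit (70.56) and Tal1 (58.21) were KO only, and Zfp36l2 (122.39) and Meis1 (53.88) were WT only. With equal numbers of peaks, WT and KO had 25 and 21 ribosomal proteins, 8 and 6 quiescence and 3 and 0 HSC identity genes. Chromatin writers and erasers then had 7 and 5, OXPHOS 18 and 18, and MNK, ERK and eIF4E signalling 5 and 5. P-TEFb and elongation had 10 and 11, and interferon response 4 and 5. Glycolysis had 0 and 4, autophagy and lysosome 4 and 8, and receptors and PI3K signalling 4 and 7.

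Markers of other cell types had MYC peaks at 0 and 2 of 29 myeloid, 0 and 2 of 22 B cell, 2 and 4 of 27 T and NK, 5 and 4 of 20 megakaryocyte, and 1 and 3 of 20 stromal and endothelial genes in WT and KO. Olfactory receptors, silent in blood, had 8 and 9 of 1106, at percentile 0.0 for KO-only genes but at 22.3 among ends with H3K4me3. The peaks at Nat10, Zfp36l2 and Kdm6b overlapped a peak of the other genotype outside the window. Peaks at some of the named genes, such as Nop16, Mcm7, Aurka and Uqcrh, also lay at an end of a neighbouring gene. The highest KO-only scores were at Lypd4 (639.21), at the peak shared by Dnajc3 and Uggt2 (569.5), at the peak shared by Ankrd34a and Polr3gl (483.79), and at Them7 (405.64), Adgb (393.37) and Tmem229a (356.36). Of these, Lypd4, Them7, Adgb and Tmem229a had no H3K4me3 at that end in either genotype. The highest WT-only scores were at Obp2b (268.44), Ctla2a (238.28), Olfr769 (237.59) and Paqr7 (234.98), and the peaks at Olfr769 and Paqr7 overlapped a KO peak outside the window.

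**Figure D3:**
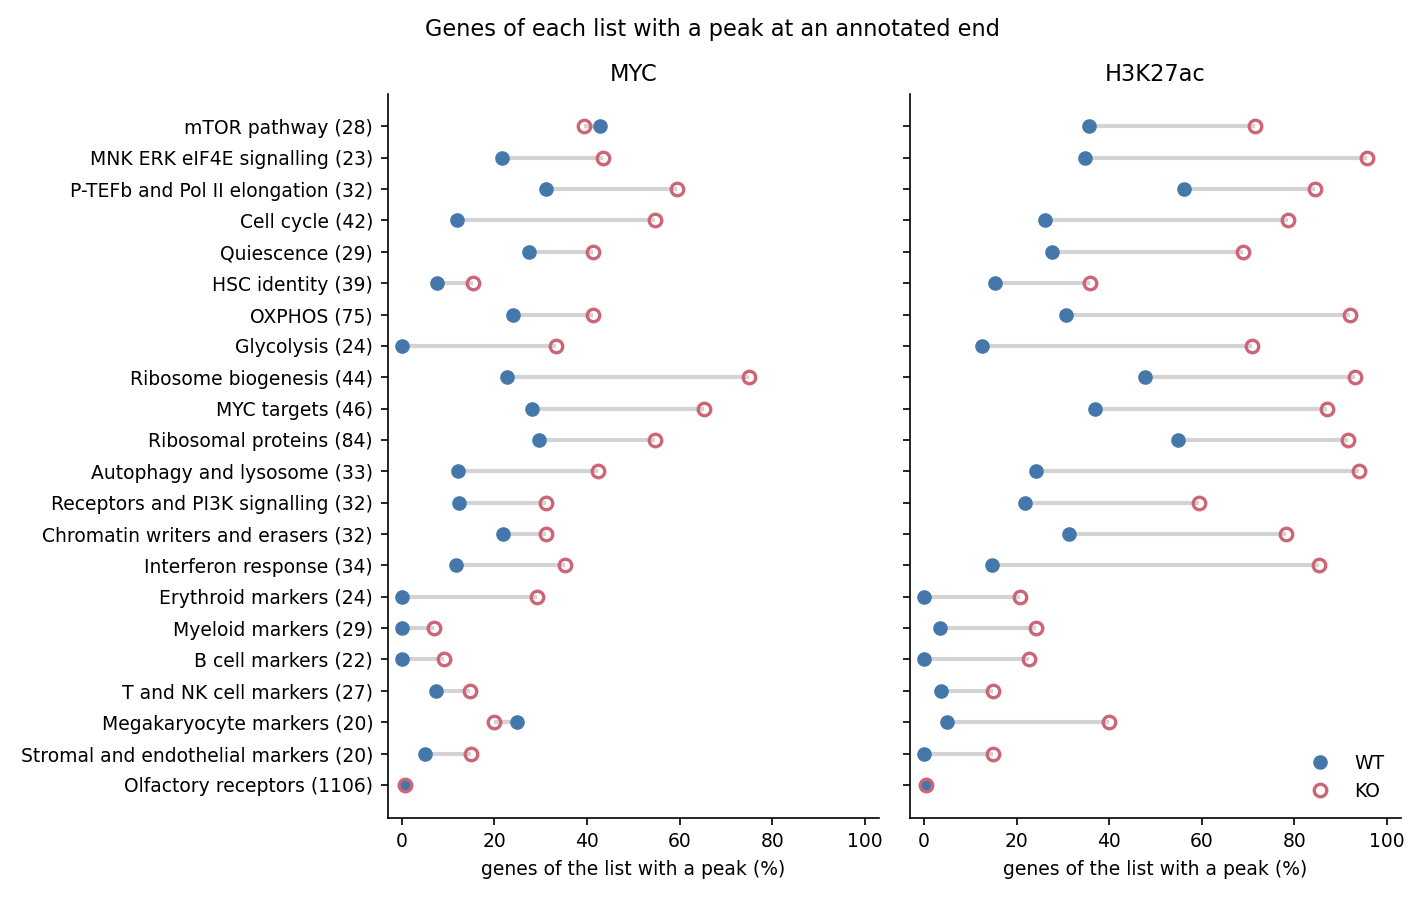
Percent of the genes of each fixed list (number of genes in brackets) with a MYC peak (left) or an H3K27ac peak (right) within 1 kb of an annotated end, in WT (filled) and KO (open). Ribosome biogenesis had the highest KO value for MYC (33 of 44 genes), and the mTOR pathway and megakaryocyte lists were the ones with a lower value in KO than in WT, by 1 gene each. Without Mtor, the targeted gene, the mTOR pathway list had 11 genes in either.

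MYC peaks in both genotypes lay at marked or open regions far more often than random placements. In KO, 46.9% (CI 46.2 to 47.5) of peaks overlapped an H3K27ac, H3K4me3 or ATAC-seq peak of the same genotype, against 4.99% of random placements, and in WT 60.5% (59.5 to 61.5) did so, against 4.34%. The 3911 KO peaks shared with WT reached 87.0%, and the 18175 KO-only peaks 38.2%, which was 7.96 times their random share. Genes with H3K27ac more often had a KO-only MYC peak: 33.1% (CI 31.4 to 34.8) of the 2983 genes with H3K27ac in both genotypes, 27.8% (26.7 to 29.0) of the 5573 with it in KO only, and 4.23% (3.89 to 4.59) of the 12909 without it. Genes KO only for both MYC and H3K27ac numbered 1551, where independent lists would share 803. Among genes with H3K27ac in KO the independent number was 1654, so the excess was absent once genes without H3K27ac were set aside.

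Only 11 genes were KO only for MYC, H3K27ac and H3K4me3 together. The 10 with the highest MYC scores were Hsd17b14 (141.92), the guanylate-binding GTPase gene Gbp9 (120.49), the kinesin gene Kif5c (90.01), Serp2 (87.56), Dnajc1 (75.19), Kbtbd7 (73.19), Mrgpra2b (70.48), Chmp2a (66.96), Tesmin (62.85) and the platelet glycoprotein gene Gp1ba (59.94). At Kif5c and Serp2 the H3K4me3 peak lay at the opposite end from the other peaks, and at Hsd17b14, Dnajc1 and Chmp2a it overlapped a WT H3K4me3 peak.

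H3K4me3 was compared to ask whether the set of active promoters differs between the genotypes, and it was much alike. Of the WT peaks, 93.3% (CI 92.9 to 93.7) overlapped a KO peak, and 87.1% (86.6 to 87.6) of KO peaks overlapped a WT peak. A peak lay at an end of 11438 genes in WT and 11746 in KO, of which 11109 were shared, 637 KO only and 329 WT only. At 147 of the 637 genes the KO peak overlapped a WT peak that lay outside the window. KO peaks were wider in general, with a median of 2608 bp against 2184 bp. The ratio of KO-only to WT-only genes was 1.94, and 1.23 with equal numbers of peaks.

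Of the 22 lists, 9 had no gene with H3K4me3 in WT only and 13 had at least 1. Among the 9, OXPHOS had them at 72 of 75 genes in both genotypes, ribosome biogenesis at 43 of 44, autophagy and lysosome at 33 of 33, glycolysis at 21 of 24 and P-TEFb and elongation at 29 of 32. A group of WT-only genes stood out when the lists were inspected, a comparison not fixed beforehand, and its genes were chosen after their values were seen. HSC identity genes had a peak at 29 of 39 in WT and 24 in KO, and Fli1, Hoxa10, Ikzf1, Kit and Zfp36l2 were among those in WT only. The quiescence list had 23 of 29 and 20, with the forkhead factor gene Foxo3, Gfi1, Trp53 and Txnip among those in WT only, and the cell cycle list 40 of 42 and 36, with Ccnd2, Ccnd3, Mcm2 and Pcna in WT only. Ribosomal proteins had 79 of 84 in WT and 76 in KO, and megakaryocyte markers 10 of 20 and 9. Myc, Eif5a and Set of the MYC targets, and Ank1, Car1 and Car2 of the erythroid markers, were also WT only.

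The 34 WT-only genes of the fixed lists had WT peaks with a median width of 5352 bp, against 2650 bp for genes that kept a peak. At 18 of them the WT peak was 5 kb or wider, as at Kit (7324 bp), Ikzf1 (7489 bp) and Pcna (8536 bp), and at 7 it was under 2 kb, as at Ank1 (573 bp), Hoxa10 (753 bp) and Mcm2 (1581 bp). Counted at either end, 33 of these 34 genes had an ATAC-seq peak in WT 2 and 32 in KO 2, 23 in WT 1 and 23 in KO 1. An H3K27ac peak in KO lay at either end of 23 of them. The share of WT peaks without a KO peak was 29.0% (CI 27.1 to 30.9) at widths under 1 kb, 0.861% (0.613 to 1.17) at 2 to 3 kb, 0.941% (0.597 to 1.41) at 3 to 4 kb, 6.46% (4.14 to 9.54) at 5 to 6 kb, 41.3% (29.0 to 54.4) at 7 to 8 kb, and 76.0% (54.9 to 90.6) of 25 peaks at 8 kb or more. The widest peak of either list was 8767 bp in WT and 8704 bp in KO. Against unmatched random lists, the WT-only share lay at percentile 100.0 for HSC identity and quiescence and at 99.77 for cell cycle. Against random lists matched on WT peak width, a comparison chosen after these values were seen, it lay at 82.6, 96.8 and 96.4.

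**Figure D4:**
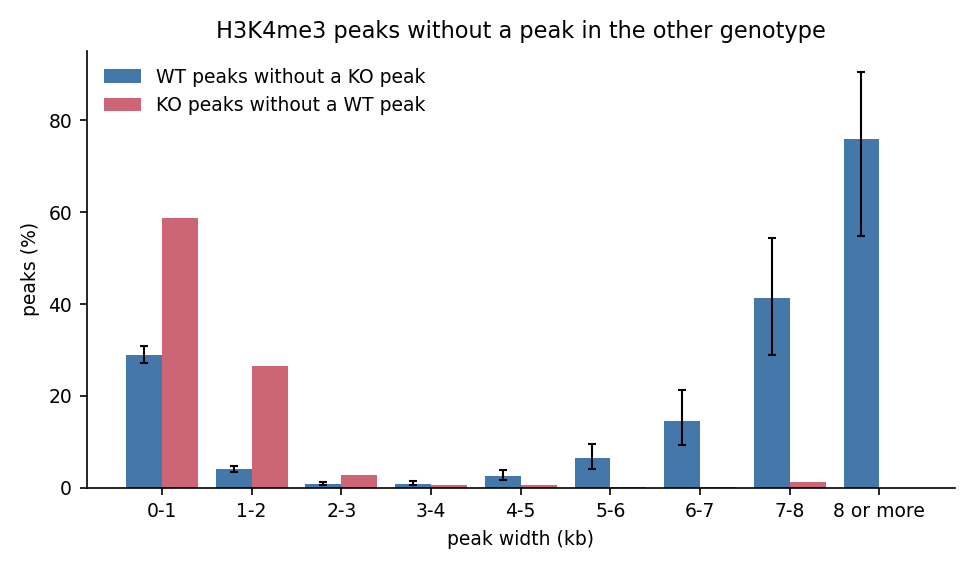
Percent of H3K4me3 peaks that had no overlapping peak in the other genotype, by peak width in kb, for WT (blue, with 95% Clopper-Pearson intervals) and KO (red, without intervals). For WT peaks the share fell to 0.861% at 2 to 3 kb and reached 76.0% at 8 kb or more.

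The highest-scoring H3K4me3 genes in WT only were the interferon-induced GTPase gene Gvin1 (911.12), Serinc3 (652.23), the calreticulin gene Calr (597.52) and the ribosomal protein gene Rpl7a (577.5). All 4 had ATAC-seq peaks in all 6 libraries and an H3K27ac peak in KO. The highest in KO only were Cpeb1 (941.87), Apc2 (797.42), Klb (790.49), Masp2 (771.47), Ddx56 (767.75), Trim66 (714.94), Stx18 (697.52) and Mmadhc (682.46). Each of these 8 KO peaks overlapped a WT peak, and those at Apc2, Klb, Masp2 and Trim66 belonged also to the neighbouring genes Rps15, Rpl9, Srm and Rpl27a.

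ATAC-seq was compared between WT and KO to ask which regions open or close without mTOR. Open chromatin was largely shared, and no gene of the 22 lists, taking both ends together, was open in both libraries of 1 genotype and neither of the other. Taken by itself, the lower end of Mtor, the floxed gene, had a peak in both WT libraries and neither KO library, but its upper end had one in KO 2. Sequence removed by Cre gives no peak, so the lower end cannot be called closed in KO. Of the 85640 regions, 150 were open in both KO and neither WT library and 113 in both WT and neither KO library, a ratio of 1.33. At gene ends, 6 genes were open in KO only, among them the GABA transporter gene Slc6a11, Rtn2, the growth factor gene Epgn, Tmem268 and the receptor kinase gene Grk2, with scores between 50.87 and 286.97. Gzf1, Duxf3, Sigirr and Gstm3 were open in WT only, and 2210010C04Rik made the fifth, which the naming rule leaves out. At Gzf1, Sigirr and Gstm3 the WT peaks overlapped a KO library's peak that ended outside the window.

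These counts did not exceed those of an arbitrary pairing. Splitting the 4 libraries into WT 1 with KO 2 against WT 2 with KO 1 gave 51 and 222 regions, a sum of 273 against 263 for the genotypes, and splitting the second from the first libraries gave 31857 and 23. The KO to WT ratio depended on single libraries: it was 0.0143 without WT 1, 18.5 without WT 2, 127 without KO 1 and 0.112 without KO 2, settings that set a short list against long ones. It was 0.801 with equal numbers of peaks. In comparisons added after the values were seen, it was 1.43 between the first libraries and 1.31 between the second.

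KO MycHet libraries were set beside these regions to ask whether regions open in KO stay open with 1 floxed c-Myc allele. Of the 150 KO regions, 45 (30.0%, CI 22.8 to 38.0) were open in both KO MycHet libraries and 69 in neither, and of the 113 WT regions 17 (15.0%, CI 9.01 to 23.0) were open in both and 63 in neither. Of the 12652 regions open in all 4 WT and KO libraries, 99.4% (CI 99.2 to 99.5) were open in both. These sets were not matched on score, so the lower share cannot be read as a loss in KO MycHet. With peaks at or above the pooled median score of 125.69 only, 7 regions were KO only and 5 WT only. Among regions in KO 2 and not WT 2, the share open in both KO MycHet libraries was 4.09% at scores of 50 to 60 and 87.7% at 200 or more. Rtn2, Tmem268 and Grk2 were open in both KO MycHet libraries, and Slc6a11 and Epgn in neither. The 30.0% became 86.2% without WT 2, 17.5% without KO 1 and 10.9% without KO 2. Leaving out a KO MycHet library loosens the measure and cannot lower it: 36.0% were open in KO MycHet 1 and 48.0% in KO MycHet 2.

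The second libraries, WT 2 and KO 2, had lists of similar length. Of 16133 regions in KO 2 and not WT 2, 17.5% (CI 16.9 to 18.1) were open in both KO MycHet libraries, against 5.83% (5.42 to 6.26) of 12298 regions in WT 2 and not KO 2. Among regions scoring 200 or more, the shares were 87.7% (84.8 to 90.2) of 602 and 40.9% (31.6 to 50.7) of 110. The first libraries gave no difference in that direction, with 79.6% of 5801 regions in KO 1 and not WT 1 and 81.2% of 4068 regions in WT 1 and not KO 1. Each comparison rests on 1 WT and 1 KO library, so there is no spread between libraries, the intervals cover regions only, and a peculiarity of WT 2 is not separated from genotype. Both comparisons, and the score classes, were chosen after the values were seen.

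**Figure D5:**
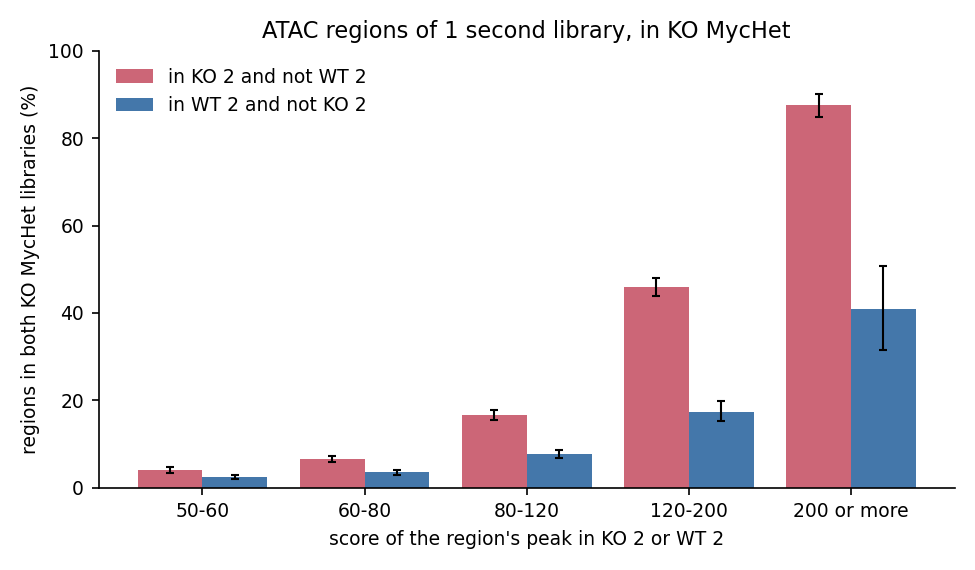
Percent of ATAC-seq regions found in both KO MycHet libraries, by score of the region's peak, for regions in KO 2 and not WT 2 (red) and in WT 2 and not KO 2 (blue), with 95% Clopper-Pearson intervals. In the highest class the shares were 87.7% and 40.9%.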

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

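The alternatives that used gene ends with H3K4me3 in both genotypes, peaks without overlap in the other genotype, 1 WT and 1 KO ATAC-seq library, and random lists matched on H3K4me3 score were chosen after seeing the data, and the others were fixed beforehand. The KO lists stayed longer, and KO-only genes stayed more numerous, for all 3 ChIP targets under every alternative run. The H3K27ac peak ratio of 1.99 became 4.49 at or above the pooled median score and 6.66 by covered length. The H3K27ac gene ratio of 33.6 became 10.3 with equal numbers of peaks (3977 KO-only and 385 WT-only genes), 20.8 with a 2.5 kb window, 123 at or above the pooled median score and 57.2 at ends with H3K4me3. The H3K4me3 gene ratio of 1.94 became 1.23 with equal numbers and 1.27 at or above the pooled median score. The MYC gene ratio of 6.12 became 1.24 with equal numbers, which by construction removes the difference in list length. The cause was not tested for the other shifts.

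For MYC, 4 gene lists stood above random lists, 9 did without matching and 2 at ends with H3K4me3. For H3K27ac, 4 lists did so, and 2 with equal numbers of peaks. The share of KO MYC peaks at marked regions (46.9%) was 45.4% when an overlap of 50% of the shorter peak was asked for and 54.3% with equal numbers, and the WT share (60.5%) was 58.8% with the stricter overlap.

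The ATAC-seq ratio of 1.33 reversed to 0.801 with equal numbers of peaks, to 0.0143 without WT 1 and to 0.112 without KO 2, and leaving out 1 library gave 0.0143 to 127. It was 1.43 between the first WT and KO libraries and 1.31 between the second. The share of KO-only regions open in both KO MycHet libraries (30.0%) was 47.7% with equal numbers, 17.5% with WT 2 and KO 2 as the only WT and KO libraries, and 10.9% to 86.2% when 1 library was left out. The lengths of the lists left in each group, 17303 to 72149 peaks, differ by construction when 1 library is left out. A count or ratio was taken as unchanged within 1.5 times its value, a share of MYC peaks within its 95% CI, and the KO MycHet share within 1 SD of its 2 libraries. By these limits, 30 comparisons of main results stayed close to their value, 23 moved and 3 reversed. Among the percentiles of single lists, 31 kept their side of the threshold and 14 did not. Read depth is unknown, so what depth limits could not be measured. No paired analysis was possible because the ATAC-seq labels of the 3 groups share only the number 2, each ChIP target has 1 library per genotype, and the RNA-seq samples were not analysed here.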

Other observations

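The comparisons with equal numbers of peaks were fixed beforehand. All other tests in this part were chosen after the results were seen, as were the limits that decided every test, the score level, width classes and gene sets they use and the regions named.

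A set of ATAC-seq regions was missing from WT 2 and strong in the other long lists. Among the 4 longer lists (WT 2, KO 2 and both KO MycHet libraries), 179 regions had no peak in WT 2 and scored 150 or more in the other 3. The same count was 2 for regions missing from KO 2, 26 for KO MycHet 1 and 5 for KO MycHet 2. Ordered by the lowest of these 3 scores, the first of those with no WT 1 peak lay inside Mtmr7 (chromosome 8, 40594701 to 40595951; lowest score 416.8), inside Gng12 (chromosome 6, 67013978 to 67015272; 350.76), 9346 bp from Clec16a (340.08), and inside the netrin receptor gene Dcc (321.14). A further such region lay inside the histone deacetylase gene Hdac4 (276.28). Of the 179, 6 lay at gene ends (3.35%, CI 1.24 to 7.15), against 32.8% of the 37313 regions in all 4 lists. WT 1 had a peak in 4 of them and KO 1 in 7, 8 had an H3K27ac peak in KO and 14 a MYC peak in KO. In the reverse direction, the highest-scoring region of WT 2 that none of the other 3 had was the lower end of Mtor (1418), followed by a region at 250.1.

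MYC peaks were sparse on the X chromosome. It held 0.956% of the WT and 1.35% of the KO MYC peaks, against 2.23% to 3.47% of the peaks in the other 10 libraries. These shares are of all listed peaks, those on chromosome Y included.

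The KO library had more and wider H3K27ac peaks, and most of its KO-only peaks lay at regions open in both WT 2 and KO 2. Newly opened regions are argued against as the cause, since 3.02% of the KO-only peaks were open in KO 2 and not in WT 2. A lower signal over background in the WT library may account for part of the pattern, because 54.0% of WT peaks lay in open chromatin of WT 2 and 79.7% of KO peaks in that of KO 2. Overlap was counted at 1 bp, however, so wider peaks overlap more often, and the median width was 1237 bp in KO against 333 bp in WT. A rise of acetylation at active promoters without mTOR, where 81.0% carried a peak in KO and 31.8% in WT, cannot be told apart from a lower WT signal with 1 library per genotype. It would take further libraries of each genotype to separate them.

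MYC peaks lay at more gene ends in KO than in WT. Of the KO-only MYC peaks, 38.2% overlapped marked regions, 7.96 times the share of random placements. This does not decide on background calls, because placements were spread evenly and background that gathers in open chromatin would exceed them too. The longer KO list may account for the number of genes, as the KO-only to WT-only ratio was 1.24 with equal numbers of peaks, though a real gain in binding would lengthen the list too. It does not account for the high rank of the ribosome biogenesis list, which lay at percentile 99.78 with equal numbers. The KO-only genes of that list fell from 26 to 13 there, so list length may account for part of their number. With 1 library per genotype, a difference between single libraries stays open, and further libraries of each genotype would be needed to test it.

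H3K4me3 peaks at 34 genes of the fixed lists, including Kit, Ikzf1 and Myc, were found in WT only. At either end, 94.1% of the genes had an ATAC-seq peak in KO 2 and 97.1% in WT 2, and 67.6% had one in KO 1 as in WT 1. This does not decide whether these promoters closed, because the open end need not be the end with the H3K4me3 peak. Of all 90 WT peaks of 5 kb or more without a KO peak, 100.0% overlapped an ATAC-seq peak of KO 2 and 98.9% one of WT 2. The shares were 90.0% for KO 1 and 84.4% for WT 1, which argues against closing throughout these wide regions. An upper limit on the width of called peaks may account for the 9 genes with WT peaks of 8 kb or more, since 76.0% of WT peaks of 8 kb or more had no KO peak, against 0.861% of those of 2 to 3 kb, and it stays open for the 18 genes with WT peaks of 2 to 8 kb, where the share went from 0.941% at 3 to 4 kb to 41.3% at 7 to 8 kb. It does not account for the 7 with WT peaks under 2 kb: 12.6% of all such peaks had no KO peak, and where they had one, it reached 7 kb in 0.0173%. A loss at stem cell genes beyond that of their width cannot be told apart from this limit without the read coverage, not used here, with the HSC identity list at percentile 82.6 among lists matched on width.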
